A study of Mus musculus with 6 samples.

How the data were processed

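RNA was measured in 6 pieces of mouse liver from 3 animals. The animals, called L-NICD in the labels, overexpress Notch and were fed a diet that produces non-alcoholic steatohepatitis (NASH) for 16 weeks. Each mouse gave 1 tumour and 1 piece of the surrounding non-tumour liver. Groups and mouse numbers came from the sample titles. Libraries were made with an mRNA TruSeq kit, per the labels' protocols. The kit name given does not state whether strand was kept, so it is not known whether reads of overlapping and antisense genes were told apart.

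The deposited count table holds whole-number counts per gene symbol, 1 column per library. The submitters' processing notes name STAR, HTSeq, featureCounts and DESeq2, and the builds GRCm38 and mm10, without versions or the role of each tool. The authors also deposited normalized counts, a signal-type unit. Dividing the counts by these values gave 1 factor per library, between 0.822 and 1.10, the same for every gene. Another deposited table holds the authors' mean signal, log2 fold change and its standard error, a test score, and p-values with adjusted p-values. None of its columns names the libraries used. The mean signal was therefore recomputed for 40 subsets of the 6 libraries. The only subset that matched was the one of 5 libraries without tumour 2, with a largest relative difference of 4.82e-15. DESeq2 without a block on these 5 libraries gave the log2 fold changes of the authors' deposited table to within 1.31e-07. Why tumour 2 was left out is not given in the sources used here.

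The count table has 30021 rows, of which 108 repeat a symbol. In 91 cases the repeat held identical counts and was dropped (at most 0.179% of the counts of a library). Total counts ran from 19133326 to 23925382 per library. Relative counting error is larger for genes with low counts and for smaller libraries.

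Genes were kept by filterByExpr of edgeR at its default minimum count of 10, which left 14052. Tumours were compared with non-tumour livers by the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) after TMM scaling, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use the TMM-scaled library sizes, and log2 CPM a prior count of 2. Standard errors of log2 fold changes were taken as the fold change divided by the square root of the F statistic. Before the data were examined, 32 gene lists were written down, covering Notch signalling, cholangiocytes, liver tumours, cell division, hepatocyte functions, inflammation, other cell types and RNA quality. The 31 lists with at least 3 tested members were tested by camera of limma 3.58.1 with a preset correlation of 0.01, then with an estimated correlation, and by fry. Counts of list members past the threshold were made over all genes and adjusted over the list alone. Several lists share members, such as Cyp2e1 and Cyp1a2 in the drug-metabolising and the pericentral list.

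The main design had no block, because no protocol in the labels states one. Both tissues of a mouse come from the same animal, so the mouse numbers pair the samples, and a fit with the mouse as a block is given where it changes a call. Without tumour 2, mouse 2 has only its liver. The block fit of those 5 libraries therefore compares tumour with liver in mice 1 and 3 alone. The correlations of the deviations from the group means were 0.317, -0.03 and 0.04 for mice 1, 2 and 3, across genes. Within the tumours the deviations of tumour 2 ran against those of tumours 1 and 3 (-0.63 and -0.72). Within the livers those of non-tumour liver 3 ran against livers 1 and 2 (-0.77 and -0.82). Both libraries weigh on the values per mouse, which therefore cannot show how strong the pairing is.

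Genes were named by a rule written before the data were examined: Notch1, then the 6 largest changes per direction among called genes with an average log2 CPM of at least 2 and the same direction in every mouse, then the 2 members of each list with the smallest p (4 in the Notch and cholangiocyte lists), and 7 further genes. Predicted genes, mitochondrially encoded genes and antigen-receptor segments were left out of the largest changes. No gene passed in the comparison of 6 libraries. After the data were examined, the whole rule was therefore repeated on the 5 libraries of the authors' deposited table, with mice 1 and 3 and with the average log2 CPM of these 5 libraries. With the average over all 6 libraries, 10 of the 12 largest changes would be named as well, and Nebl and Vil1 would take the place of Kntc1 and Bhlha15, whose averages over 6 libraries are 1.82 and 1.84. List members outside the rule that are named in the text were chosen after their values were seen.

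Positions are those of GENCODE M21 on GRCm38, matched by symbol for 99.7% of rows. Transcript lengths from this annotation covered 99.8% of tested genes. Alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, a test against a fold of 1.5, and leaving out each library or mouse. Added after seeing the data were the comparison of 5 libraries and an offset for the trend of counts with transcript length in each library.

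The procedure was tested on simulated counts for the same 14052 genes. With 6 libraries edgeR recovered 17.9% of 2-fold, 86.6% of 4-fold and 98.5% of 8-fold changes. With 5 libraries it recovered 13.4%, 77.6% and 95.5%. Every simulated tumour carried the full change, and the libraries of these runs otherwise shared the same expected level per gene. These shares need not hold for the real libraries. The changed list was found, and 0 of 30 unchanged lists were called. Simulated genes were drawn independently, so this could not show false calls of lists whose members vary together. In the 6 real libraries the estimated correlation of the cell cycle list was 0.884. A length trend added to 1 simulated library (rho = -0.559) was removed by the offset (rho = 0.001).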

Results

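Gene expression was measured by RNA sequencing in 3 liver tumours and in the surrounding non-tumour liver of the same 3 L-NICD mice after 16 weeks on the NASH diet. Total counts were 23925382, 21583815 and 20618704 in non-tumour livers 1 to 3 and 19133326, 22347694 and 20331972 in tumours 1 to 3. Tumours 1 and 3 lay on one side of the first principal component, which carried 54.1% of the variance, and tumour 2 lay beside non-tumour livers 1 and 2. The log2 CPM of tumour 2 correlated best with that of the liver of its own mouse (r = 0.984, across genes), whereas tumours 1 and 3 correlated with each other at 0.969. Set against counting noise, tumour 2 and its liver had a chi-square per degree of freedom of 19.02, the lowest of all pairs of libraries (next 50.7, highest 369.9). Non-tumour liver 3 stood apart from the other livers, with 2.81% of its counts in ribosomal protein genes against 1.36% to 1.69% in the other 5 libraries.

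**Figure D1:**
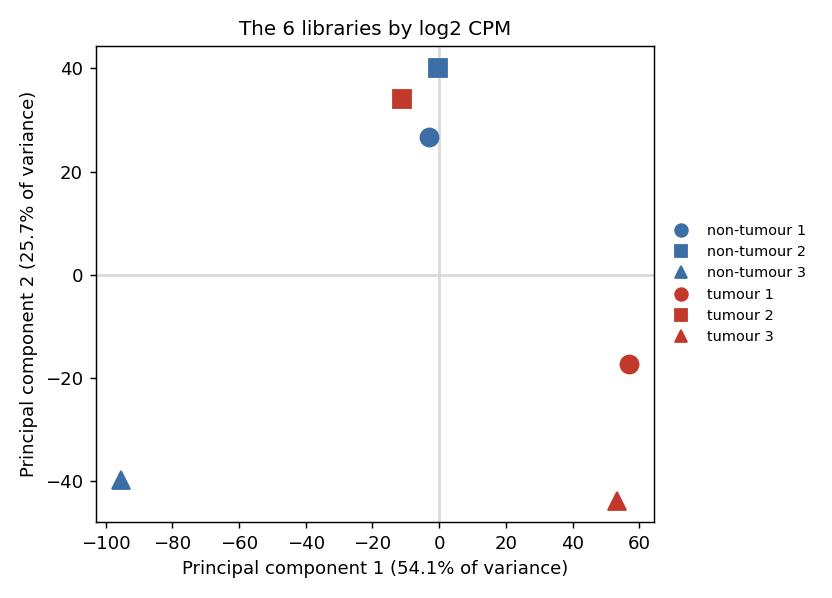
The 6 libraries on the first and second principal components of log2 CPM (percent of variance on each axis), coloured by tissue and with 1 marker shape per mouse. Tumours 1 and 3 sit at 56.8 and 53.3 on the first component, tumour 2 at -11.3 beside non-tumour livers 1 and 2, and non-tumour liver 3 at -95.3.

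Notch1, the receptor whose intracellular domain carries the Notch signal into the nucleus, was present in all libraries. Its level was 37.9, 47.5 and 22.8 CPM in non-tumour livers 1 to 3 and 95.5, 42.0 and 64.5 CPM in tumours 1 to 3. Notch1 lies on chromosome 2 from 26457903 to 26516663 (GRCm38). Tumours 1 and 3 were above the non-tumour liver of the same mouse and tumour 2 was below it. The log2 fold change over the 6 libraries was 0.90 ± 0.37 (SE), which did not pass edgeR's test (adjusted p = 0.558). Counts per gene do not separate the introduced sequence from the gene of the mouse itself.

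The first comparison asked which transcripts differ between all 3 tumours and the 3 livers around them. Genes of cell division had the largest mean difference of the lists tested upward: all 21 tested members had a positive log2 fold change, with a median of 1.86. Mki67, a marker of dividing cells, was at 5.21, 4.50 and 3.19 CPM in the livers and at 49.999, 5.95 and 29.3 CPM in the tumours. Enzymes of drug metabolism and of bile acid synthesis and transport lay on the other side, with negative values in 17 of 17 and 16 of 16 tested members. Cyp3a11, a major drug-oxidising enzyme, was at 4896, 2040 and 5450 CPM in the livers and at 1042, 2668 and 736 CPM in the tumours.

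No single gene passed the threshold in edgeR (0 higher and 0 lower of 14052, smallest adjusted p 0.558). At an unadjusted p under 0.05 there were 1079 genes, 775 higher and 304 lower, against 702.6 expected by chance. DESeq2 called 79 higher and 1 lower, and limma-voom called 0 with 792 genes at an unadjusted p under 0.05. With the mouse as a block edgeR called 0 and 613 genes had an unadjusted p under 0.05. Within the cell cycle list, 16 of 21 members passed when adjusted over the list alone and 0 over all genes tested.

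By camera with the preset correlation, 15 of 31 lists passed, 4 toward higher and 11 toward lower values. With an estimated correlation none did (smallest adjusted p = 0.572), and fry called 0. Other groupings of the same 6 libraries, which mix tumours and livers, passed from 2 to 13 lists by the preset test. The cell cycle list had an adjusted p of 1.03e-14 and the drug-metabolising list 1.01e-06, both with an adjusted p = 0.572 with an estimated correlation. The Notch list passed in the preset test (adjusted p = 0.0225, and adjusted p = 0.572 with an estimated correlation) but not with the length offset (adjusted p = 0.109). Of its 19 tested members 14 were positive, among them Notch3 (log2 fold change 1.18 ± 0.37) and Nrarp (1.72 ± 0.64), a feedback target of Notch signalling, neither past the threshold. Hes1, Hey1 and Heyl, direct targets of Notch in many tissues, had log2 fold changes of 0.47 ± 0.37, -0.11 ± 0.36 and -0.11 ± 0.30. Also past the threshold with the preset correlation were the lists of liver tumour and fetal liver markers and of immediate-early genes toward higher values (adjusted p = 0.0397 for both). Toward lower values were those of male-biased genes (0.00171), fatty acid synthesis (0.00256), pericentral genes and amino acid breakdown (0.00899 for both), fatty acid oxidation (0.0128), and glycolysis and antioxidant targets (0.0363 for both). For these lists the adjusted p was between 0.572 and 0.589 with an estimated correlation. With the mouse as a block 11 lists passed, and the tumour marker, immediate-early, antioxidant and erythroid lists no longer did (adjusted p = 0.0852, 0.0663, 0.0502 and 0.0502).

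Transcripts encoded by the mitochondrial genome were negative in 12 of 13 members (preset adjusted p = 0.0225, and adjusted p = 0.572 with an estimated correlation and 0.449 with the length offset). They took 8.82%, 7.05% and 6.26% of the counts in the livers and 5.60%, 8.02% and 5.49% in the tumours. Markers of macrophages, of T and NK cells, of B and plasma cells, of neutrophils and of endothelium did not pass (preset adjusted p from 0.145 to 0.803), nor did the hepatocyte, periportal, female-biased, cholesterol, acute-phase, cytokine, antigen presentation, stellate, Hippo, cholangiocyte and pancreatic or adipocyte lists (0.0843 to 0.816). The 6 erythroid genes tested were all negative (preset adjusted p = 0.0397, and adjusted p = 0.572 with an estimated correlation and 0.384 with the length offset). With the length offset the cytokine and antigen presentation lists passed the preset test (adjusted p = 0.0262 for both).

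**Figure D2:**
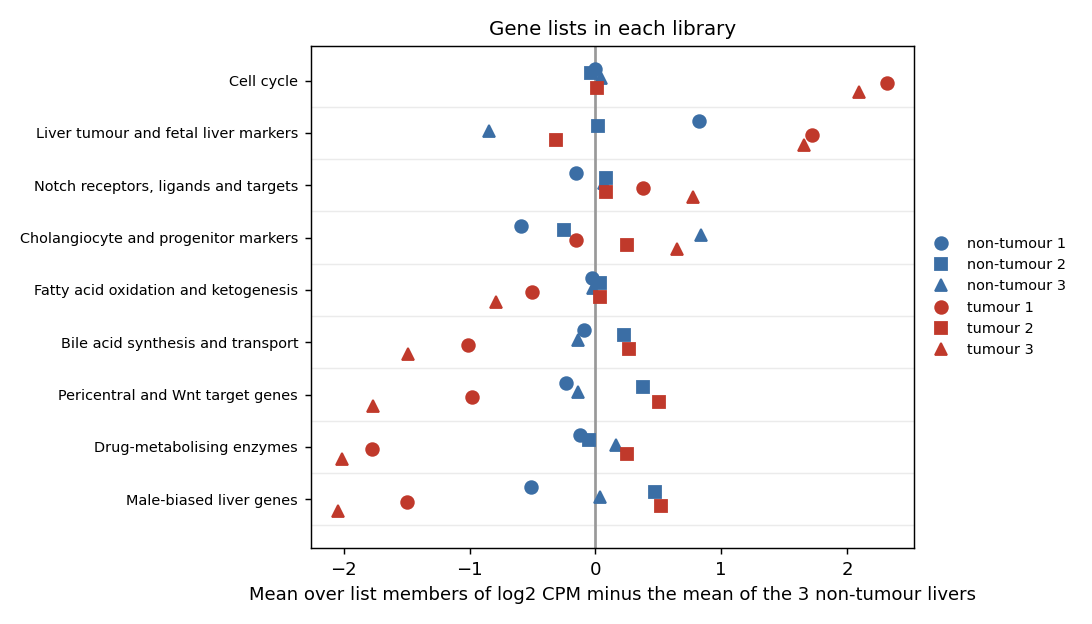
Mean over the members of 9 gene lists of the log2 CPM minus the mean of the 3 non-tumour livers (horizontal axis, log2 units), 1 point per library. For the cell cycle list tumours 1 and 3 lie at 2.32 and 2.10 and tumour 2 at 0.01, and for the drug-metabolising list they lie at -1.78, -2.02 and 0.25.

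The second comparison used the 5 libraries of the authors' deposited table, tumours 1 and 3 against the 3 non-tumour livers. In it 272 genes rose and 92 fell in edgeR, and genes of DNA replication and cell division were among those that rose. Uhrf1, which keeps DNA methylation at replicated DNA, rose from 2.81 ± 0.36 CPM (SD, n = 3) to 53.3 ± 2.31 CPM (SD, n = 2), a log2 fold change of 4.24 ± 0.23 (SE). Among the genes that fell was Nr1i3, a nuclear receptor that induces drug metabolism, which fell by 2.37 on the log2 scale (SE 0.26). Tumour 2, which did not enter this test, had 2.79 CPM of Uhrf1 and 666.9 CPM of Nr1i3, and the livers had 444 to 492 CPM of Nr1i3.

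Of the cell cycle list 21 of 21 members were positive, and 15 rose over all genes tested (21 adjusted over the list alone). Mcm6 and Mcm5, subunits of the replicative helicase, rose by 3.15 ± 0.22 and 3.34 ± 0.27 on the log2 scale, and Mki67 by 3.20 ± 0.34 (adjusted p = 0.0135, 0.016 and 0.0194). The list had a preset adjusted p of 1.36e-34, and an adjusted p = 0.0884 with an estimated correlation. Fry gave 0.00623. The other genes with the largest changes upward were Mogat2, an acyltransferase of triglyceride synthesis (4.91 ± 0.75), Kntc1, a kinetochore protein (4.81 ± 0.47), Sult4a1 (4.05 ± 0.44), Dtl, a ubiquitin ligase adaptor of DNA replication (4.04 ± 0.29), and Bhlha15, a transcription factor of secretory cells (3.95 ± 0.68). Kntc1 and Bhlha15 were below 1 CPM in each of the 3 livers. The 2 tumours differed in Mogat2 (8.87 and 37.0 CPM in tumours 1 and 3) and in Bhlha15 (3.30 and 15.2 CPM). Kntc1 lies on chromosome 5 from 123749716 to 123821593, and Uhrf1 on chromosome 17 from 56303321 to 56323486.

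Of the drug-metabolising enzymes 17 of 17 were negative and 8 fell over all genes tested (15 adjusted over the list alone). Cyp2c29 fell by 2.67 on the log2 scale (SE 0.32), Cyp2c37 fell by 2.34 (SE 0.25) and Cyp1a2 fell by 2.32 (SE 0.30). The preset adjusted p was 1.67e-23, with adjusted p = 0.144 with an estimated correlation and 0.0129 by fry. Of the pericentral and Wnt target genes 6 of 16 fell. They included Glul, the glutamine synthetase of hepatocytes around the central vein (fell by 1.78, SE 0.24), and Notum, a secreted Wnt inhibitor (fell by 2.09, SE 0.31). For this list the preset adjusted p was 4.33e-11, with adjusted p = 0.396 with an estimated correlation. Glul lies on chromosome 1 from 153899944 to 153909723.

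Of the bile acid genes 16 of 16 were negative and 6 fell (10 adjusted over the list alone), with a preset adjusted p of 5.69e-11 and an adjusted p = 0.207 with an estimated correlation. Cyp27a1, a sterol hydroxylase, fell by 1.61 (SE 0.25) and Slc27a5, a bile acid CoA ligase, fell by 1.74 (SE 0.28). With the mouse as a block both passed no longer (adjusted p = 0.0544 and 0.0559). Male-biased liver genes were negative in 11 of 11 members and 4 fell, among them Cyp4a12a (fell by 2.35, SE 0.27) and Mup20 (fell by 2.93, SE 0.49). Their preset adjusted p was 1.89e-10, with adjusted p = 0.328 with an estimated correlation. The largest falls were those of Mup3, Mup20, Mup10, Serpina3k, Ppp1r3c and Cyp2c29, with log2 fold changes from -3.18 to -2.67. Mup, Serpina3 and Cyp2c genes belong to families of near-identical copies, so their counts are uncertain gene by gene. Ppp1r3c, which targets a phosphatase to glycogen, fell by 2.67 (SE 0.30).

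In the Notch list 13 of 19 members were positive and 1, Nrarp, rose (log2 fold change 2.19 ± 0.37, edgeR adjusted p = 0.0449). Notch1 had a log2 fold change of 1.15 ± 0.35 (adjusted p = 0.147), Notch3 1.43 ± 0.30 (adjusted p = 0.0706) and Hey2 1.504 ± 0.34 (adjusted p = 0.0802). Hes1, Hey1 and Heyl had log2 fold changes of 0.74 ± 0.32, -0.10 ± 0.40 and -0.38 ± 0.27 (adjusted p = 0.257, 0.908 and 0.450). With the length offset in edgeR Hes1 passed (0.99 ± 0.20, adjusted p = 0.0402). Notch1, Notch3, Hey2, Hey1 and Heyl did not pass with it (adjusted p from 0.0514 to 0.913). The list passed with the preset correlation (adjusted p = 0.0176, and adjusted p = 0.546 with an estimated correlation) but not with the length offset (adjusted p = 0.0638). In the authors' deposited table Notch1 had an adjusted p of 0.0408 with a log2 fold change of 1.14. Notch3 and Hey2 also passed 0.05 there (adjusted p = 0.00729 and 0.0267). Hes1, Hey1 and Heyl did not (adjusted p = 0.227, 0.931 and 0.525).

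Of the cholangiocyte and progenitor markers 9 of 18 were positive, and the list did not pass (preset adjusted p = 0.0586). Sox9, a transcription factor of bile duct and progenitor cells, rose by 1.42 ± 0.21, and Prom1, a surface marker of progenitor cells, by 2.84 ± 0.41. Sox9 did not pass with the mouse as a block (adjusted p = 0.0595). The bile duct markers Krt19, Krt7 and Cftr had log2 fold changes of -1.87 ± 0.90, -1.42 ± 0.73 and -1.15 ± 0.31 that did not pass (adjusted p = 0.292, 0.317 and 0.116). Krt19 was at 2.59, 2.63 and 13.4 CPM in livers 1 to 3 and at 0.98 and 2.39 CPM in tumours 1 and 3. Krt7 was at 3.36, 7.32 and 16.7 CPM and at 2.09 and 4.73 CPM. Both fold changes thus lean on non-tumour liver 3, whereas Cftr was at 6.03, 6.51 and 5.29 CPM and at 3.16 and 2.21 CPM. Spp1, a secreted matrix protein, stood at 3152, 2565 and 3819 CPM in the livers and at 8635 and 7515 CPM in tumours 1 and 3 (log2 fold change 1.35 ± 0.27, adjusted p = 0.0622). With the length offset in edgeR Spp1 passed (1.58 ± 0.19, adjusted p = 0.0156). Of the 14 tumour and fetal liver markers tested 10 were positive, and Scd2 and Golm1 rose (2.93 ± 0.42 and 2.94 ± 0.50). This list had a preset adjusted p of 0.00133, and an adjusted p = 0.400 with an estimated correlation. Golm1 did not pass with the mouse as a block (adjusted p = 0.0551). Afp and Gpc3, used as markers of hepatocellular carcinoma, had log2 fold changes of 0.12 ± 0.84 and 1.08 ± 0.86 that did not pass. Sox9 lies on chromosome 11 from 112782224 to 112787760.

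**Figure D3:**
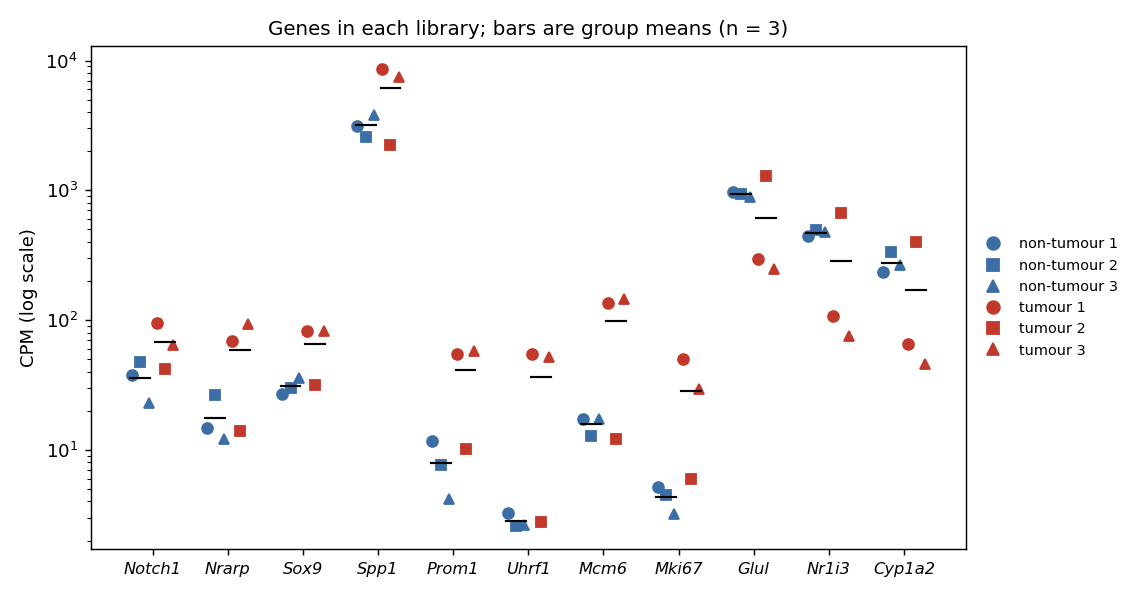
CPM of 11 genes in each library (vertical log axis), coloured by tissue and with 1 marker shape per mouse; horizontal bars are group means (n = 3). Uhrf1 is at 54.9 and 51.6 CPM in tumours 1 and 3 and at 2.79 CPM in tumour 2, beside 2.58 to 3.23 CPM in the livers.

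By the preset test 12 of 31 lists passed, 4 toward higher and 8 toward lower values, 0 of them with an estimated correlation and 4 by fry. Other groupings of the same 5 libraries, which mix tumours and livers, passed from 6 to 14 lists by the preset test. Fatty acid oxidation genes were negative in 12 of 17 members and 1, Cyp4a14, fell (preset adjusted p = 2.02e-04, and adjusted p = 0.357 with an estimated correlation). Prodh, the first enzyme of proline breakdown, was the 1 member of the urea cycle and amino acid list that fell (it fell by 1.82, SE 0.23). Lcn2, an iron-binding acute-phase protein, rose by 2.85 ± 0.46 while its list did not pass (preset adjusted p = 0.682). Col4a1, a basement membrane collagen, rose by 1.52 ± 0.22, and Psmb9 and Tap2 of antigen presentation rose by 1.37 ± 0.25 and 1.06 ± 0.19. Psmb9 and Tap2 did not pass with the mouse as a block (adjusted p = 0.0705 and 0.0937). Markers of macrophages, T and NK cells, B and plasma cells, neutrophils and endothelium did not pass (preset adjusted p from 0.434 to 0.975). Mitochondrially encoded transcripts were negative in 12 of 13 members (preset adjusted p = 0.00179, and adjusted p = 0.396 with an estimated correlation and 0.0831 with the length offset). With the length offset the cholangiocyte and hepatocyte lists (adjusted p = 0.0325 for both) and the antigen presentation list (adjusted p = 0.00183) passed the preset test. With the mouse as a block the immediate-early list did not pass (adjusted p = 0.0734, 0.0494 without), and the cholesterol list (0.00772) and the female-biased, glycolysis and macrophage lists (0.0466 each) did. In the 5 libraries the block fit rests on mice 1 and 3 only, so non-tumour liver 2 no longer enters the comparison.

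All 364 genes called by edgeR were past 0.05 in the authors' deposited table, which lists 853 genes higher and 720 lower. DESeq2 on the 5 libraries called 852 and 714. If tumour 2 was left out for its expression, the 5-library test is not independent of that choice, and with all 6 libraries edgeR called 0. Leaving out non-tumour liver 1 or 2, or tumour 1 or 3, from the 5 libraries also left 0 calls, and leaving out non-tumour liver 3 gave 906 higher and 696 lower. Without tumour 1 or 3 a single tumour remains, and the livers alone then give the spread.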

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

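The comparison of 5 libraries, with all of its alternatives, and the length offset were chosen after the data were examined. In the comparison of 6 libraries the counts of 0 genes higher and 0 lower held under other scalings, filters, limma-voom, the length offset, the block in edgeR and the test against a fold of 1.5. They changed with DESeq2 (79 higher, 1 lower), with DESeq2 and the mouse as a replicate block (38 higher, 0 lower), and without tumour 2 (272 higher, 92 lower), so the range over left-out libraries and mice was 0 to 272 higher and 0 to 92 lower. In simulated counts for 6 libraries DESeq2 called 161 genes, of which 21 were unchanged, and edgeR called 142, of which 7 were unchanged. With 5 libraries the unchanged genes were 23 of 159 calls in DESeq2 and 5 of 129 in edgeR. The cause of the differences between tools in the real libraries was not tested. The 15 lists past the threshold became 0 with an estimated correlation and 0 by fry, and ran from 9 to 15 over left-out libraries and mice. With the block 11 lists passed in edgeR and 18 in DESeq2.

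In the 5 libraries the counts of 272 higher and 92 lower became 852 and 714 with DESeq2, 633 and 509 with DESeq2 and the replicate block, 557 and 379 with the length offset, 86 and 14 against a fold of 1.5, and 106 and 38 at a minimum count of 50 (fewer genes tested). With the replicate block in edgeR they were 254 and 126. Over left-out libraries they ran from 0 to 906 and from 0 to 696, with fewer samples in each fit (a single tumour without tumour 1 or 3). The share of higher genes was 74.7% and 59.5% with the length offset. The 12 lists past the threshold became 0 with an estimated correlation, 4 by fry, 15 with the replicate block in edgeR and 18 with it in DESeq2, and ran from 9 to 15 over left-out libraries. No named gene or list past the threshold reversed its direction under the alternatives for which directions were compared. Directions were not compared for the list tests with an estimated correlation and by fry. The cause of these changes was otherwise not tested. With the replicate block in edgeR 8 named genes of the 5 libraries lost their call and 11 gained one, and in the 6 libraries 0 did. In simulated data 2-fold changes were recovered in 17.9% of cases with 6 libraries and in 13.4% with 5, and 4-fold changes in 86.6% and 77.6%. Every simulated tumour carried the change, whereas tumour 2 lay with the livers in the data. These shares therefore do not show how many changes the 6 real libraries could have missed.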

Other observations

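The symbol families, the chromosome medians and the tests on depth, a swap, the share of liver in tumour 2, transcript length in non-tumour liver 3, the length rho of tumour 3, and the splits for genes over 6 libraries and for lists over 5 were chosen after the results were seen. Among 445 families of symbols with at least 5 tested genes, cytochrome P450 genes (Cyp) were the most frequent among the genes that fell in the 5 libraries, 13 of 76 tested against 0.498 expected (Fisher's exact test, one-sided, adjusted p = 1.64e-12 over 890 tests). Carboxylesterases (Ces) followed with 5 of 14 (adjusted p = 6.11e-06) and glucuronosyltransferases (Ugt) with 4 of 17 (adjusted p = 0.000854). Among the genes that rose, Mcm helicase genes were 6 of 10 tested (adjusted p = 4.36e-06). Some members of a family, such as Cyp2c29 and Cyp2c37, share a chromosome and much of their sequence, so the members are not all independent.

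Median expression differed between chromosomes in tumours 1 and 3. Over 9173 genes with a mean log2 CPM of at least 3, the median difference from non-tumour livers 1 and 2 was 0.25 and 0.48 on chromosome 1 and 0.25 and 0.47 on chromosome 15 in tumours 1 and 3, and -0.33 and -0.28 on chromosome 13 and -0.23 and -0.22 on chromosome 4. Chromosome 14 was at -0.05 and 0.29 and chromosome X at -0.19 and -0.57. In tumour 2 the 20 medians lay between -0.06 and 0.06 (SD 0.0281, against 0.163 and 0.251 in tumours 1 and 3 and 0.0435 between non-tumour livers 1 and 2). With all 3 livers as the reference chromosome 1 was at 0.30 and 0.50 and chromosome 13 at -0.31 and -0.27.

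Technical readings of these shifts were tested. In 1000 random shuffles of genes over chromosomes, 11 chromosomes of tumour 1 and 11 of tumour 3 lay beyond the limit that 95% of shuffles stayed within, which argues against chance over independent genes. The shuffles treat genes as independent, and 4 chromosomes also passed the corresponding limit in tumour 2, 4 between non-tumour livers 1 and 2, and 3 in non-tumour liver 3 (medians from -0.16 to 0.23 over its chromosomes). Of the 22 shifts, 19 (86.4%) had both sides of the chromosome's middle gene shifted the same way by at least 0.1, which argues against clusters of neighbouring genes as the whole source. Removing trends with transcript length and GC content left at least 95.5% of the SD over chromosomes in tumours 1 and 3, against 50.6% in tumour 2, 44.2% between non-tumour livers 1 and 2, and 31.7% in non-tumour liver 3. Gains and losses of chromosomes in the tumour cells may underlie the shifts, a hypothesis that needs DNA data, and no DNA was analysed here.

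Tumour 2 lay with the livers. Its total count was 1.06 times the median of the 6 libraries, which argues against shallow sequencing. The cell cycle list in non-tumour liver 2 was -0.058 log2 units from the other livers. That argues against swapped tubes within mouse 2 only for a lesion dividing like tumours 1 and 3. A swap with a lesion whose RNA differs little from liver could not be seen by this test. The 364 genes called without it sat at a median of -0.24% of the way from the livers to tumours 1 and 3. The median was 2.33% for the 272 that rose and -7.23% for the 92 that fell. A negative value lies beyond the livers, on the side away from tumours 1 and 3. Only 54 of its genes lay 2-fold outside the range of the 3 livers, against 142 for non-tumour liver 1 and 96 for non-tumour liver 2, each set against the range of the other 2 livers and tumour 2, so a tumour with many changes of its own found no backing. The ranges for tumour 2 and non-tumour liver 2 each held the other library of mouse 2. The range for non-tumour liver 1 held no library of its own mouse, so only the 96 is a like comparison. A sample holding mostly surrounding liver is consistent with these values, and a lesion that differs little from liver in its RNA stays open.

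Non-tumour liver 3 differed from the other livers along transcript length (rho = -0.55, across genes), with median differences of 0.71 in the shortest 20% of genes and -0.59 in the longest 20%. Length alone may not account for it. The SD over genes was 1.96 times that between non-tumour livers 1 and 2, and still 1.77 times with the trend removed. Tumour 3 against tumour 1 had a rho of -0.0882, which argues against a length trend shared by both tissues of mouse 3. A difference of the whole animal apart from length was not tested. For non-tumour liver 3 the partial rank correlation with GC content was 0.208 and left GC content undecided. Of the 364 genes called in the 5 libraries 98.1% passed with the length trend removed, so these calls did not need that trend. The offset raised the calls to 936 genes, so keeping a call was easier with it and this test is weak. RNA integrity values were not used here.

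The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05 (smallest 0.1). All 10 splits called 0 genes (the real split 0, highest other 0). For lists 1 split, the real one with 15, reached that number, and the highest other split called 13, a split that grouped tumour 2 with non-tumour livers 1 and 2. The 5 libraries also make 10 splits, again too few, of which 1, the real one with 364 genes, reached that number and the highest other called 0. For lists in the 5 libraries 2 other splits passed more, 14 and 13 against 12 in the real one.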
